A study of Mus musculus with 12 samples.

How the data were processed

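Total RNA from 12 mouse tumour samples was measured on 1-colour Affymetrix arrays, with 4 arrays for each of 3 lung adenocarcinoma lines, 344SQ, 393LN and 393P. The lines were grown from tissue of a genetically engineered mouse model of lung adenocarcinoma: 393P from a primary lung tumour, 393LN from a mediastinal lymph node of the same mouse, and 344SQ from a subcutaneous site in another mouse. Per the labels, 344SQ is highly metastatic, 393LN intermediately so and 393P non-metastatic. Per the labels' protocols, RNA was isolated with an Ambion kit, checked on a NanoDrop and a Bioanalyzer, and labelled with biotin; the series' design text describes tumours grown in syngeneic mice, dissected free of the surrounding tissue and frozen.

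The values used are the probe set intensities as deposited, on a linear scale; the software that summarised and normalized them is not given in the sources used here. All values (100% within a tolerance of 1e-08 on the power) are 2 raised to a power with 2 decimals, from a floor of 1 to 21921, so the table had been on a log2 scale before deposit. The chip named in the design text is a smaller member of the family than the table's 45101 probe sets call for. Array medians lay between 7.19 and 7.29 on the log2 scale, within the tolerance of 0.25 set for using the values with no further normalization. The number of arrays limits the precision; no depth applies to this assay.

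The values were taken as log2(intensity + 16), so a fold understates the change of a gene near the floor, which is 4.09 on this scale. Of the probe sets, 34945 have 1 gene symbol in the annotation given, 932 have several, 9160 have none there and 64 are controls; only the first were used, and no symbol changed when updated through its Entrez identifier. For each of 18193 genes the probe set with the highest mean over the 12 arrays was tested, with no filter on dim ones, and a named gene's other probe sets were also tested singly. Of the genes tested, 13 were at the floor on all 12 arrays. No other columns of values were present (0).

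One model with a mean per line was fitted over the 12 arrays with limma 3.58.1 (lmFit and eBayes with the default prior) in R 4.3.3. Unless another setting is named, every adjusted p of a gene is from that fit, two-sided, with Benjamini-Hochberg adjustment over the 18193 genes. A gene is said to have risen or fallen at an adjusted p under 0.05. The adjusted p of a named gene's other probe sets are from a separate fit of the same model, adjusted over the 34945 probe sets with 1 gene symbol. The spread was shared by all 3 lines, with 9 residual degrees of freedom. The comparisons were 344SQ against 393P, 344SQ against 393LN and 393LN against 393P, and the overlap of the first and second, which share the 4 344SQ arrays. For this overlap 50 data sets with no effect were simulated, the count for independent lists was worked out, and the 344SQ arrays were split into 2 and 2.

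Fixed gene lists (35, from textbook knowledge of lung adenocarcinoma, epithelial to mesenchymal transition and the cell types a dissected tumour can hold) were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists in each comparison, then with an estimated correlation and with fry. A list's median and mean are over its measured members. Genes were named by a rule: the 10 largest rises and 10 largest falls in 344SQ against 393P and the 8 and 8 in each other comparison, among genes with an adjusted p under 0.05, no overlap of the 4 values with the other 4, and a higher mean outside the lowest 40% of group means; for each list up to 4 members with the smallest p and up to 2 in the minority direction; the 6 and 6 strongest in both 344SQ comparisons; and 14 genes fixed by name, of which 12 were tested. The result for the others is not reported here. Unnamed transcripts were skipped. A gene named outside this rule is marked as chosen after its values were seen. The groups, the tests of genes and lists, the lists, the naming rule and all but the covariate settings were fixed before the data were examined. Tests of explanations for the epithelial, interferon and Xist patterns were chosen after these were seen.

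The scripts were tested on simulated data made from the real genes' means and spread, with 200 of 18193 genes changed in each of 10 runs. The changed genes were drawn from the brightest 60%, and the noise of each gene was independent of the others. For 344SQ against 393P, 84.1% of genes changed 2-fold and 98.4% of those changed 4-fold were recovered; for 344SQ against 393LN the shares were 85.5% and 98.2%, and for 393LN against 393P 86.6% and 98.5%. The share of false calls was 4.70%, 5.31% and 5.85%. The recovery does not cover dim genes, and none of these shares covers genes that vary together.

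Alternatives were another scaling (quantile normalization, or each array centred on its median), pseudocounts of 1 and 64, leaving out the dimmest 25% or 50% of genes, other choices of probe set, an intensity trend with a robust prior, array weights, a fit on only the 8 arrays compared, a comparison of ranks, and leaving out each array in turn. The level of Xist and the ratio of 3' to 5' actin signal as covariates were added after seeing the data. The labels state no batch and no pairing of arrays. The sample numbers in the titles lie in a separate, lower range for 393LN; whether this marks a batch is not stated, and it could not be separated from the line in either comparison with 393LN. Replicate numbers follow the order of the deposit. Nothing says that the 4 samples of a line came from separate animals, so the p-values measure only the spread between these samples. Line, mouse of origin and metastatic class go together in both 344SQ comparisons and cannot be separated by these arrays. Gene positions by chromosome came from the mouse assembly GRCm38.p6.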

Results

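Gene expression was measured in tumours of 3 mouse lung adenocarcinoma lines that differ in how readily they metastasise, with 4 arrays per line. 344SQ is described as highly metastatic, 393LN as intermediately metastatic and 393P as non-metastatic. The tumours had been grown in syngeneic mice, so stromal and immune cells of the host contribute RNA beside the tumour cells. Array medians on the log2 scale ranged from 7.19 to 7.29.

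The 344SQ arrays stood apart from both 393 lines. The first principal component held 35.5% of the variance and placed the 4 344SQ arrays between -43.4 and -40.8 and the 8 arrays of the 393 lines between 10.1 and 27.4. The second held 13.8%, and its ends were 393LN replicate 3 at -38.4 and 393P replicate 1 at 39.4. Pairs of arrays of one line correlated across genes with a median r of 0.983 in 344SQ, 0.982 in 393LN and 0.983 in 393P. The median between 393LN and 393P was 0.980, and those between 344SQ and the 393 lines were 0.961 and 0.965. The ratio of 3' to 5' actin signal, a sign of RNA quality, was 1.47 on 393P replicate 1 and between 1.04 and 1.19 on the other 11 arrays.

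The comparison of 344SQ with 393P asked what sets a highly metastatic line apart from a non-metastatic one. Of 34 genes of epithelial junctions and identity, 18 were lower in 344SQ. Among them Esrp1, which directs epithelial splicing, was 134-fold lower (log2 change -7.06 ± 0.24 SE, n = 4 per line, adjusted p = 6.17e-09), and the small GTPase gene Rab25 was 52.4-fold lower (-5.71 ± 0.25, adjusted p = 6.3e-08). Other genes were far higher in 344SQ. Apob, the structural protein of lipoproteins, was 99.9-fold higher (6.64 ± 0.61, adjusted p = 3.42e-05). The surfactant protein gene Sftpb was 37.6-fold higher (5.23 ± 0.35, adjusted p = 2.9e-06) and the forkhead factor gene Foxa2 29.7-fold (4.89 ± 0.44, adjusted p = 2.99e-05). In each of these genes the 4 values of 344SQ did not overlap the 4 of 393P, which the naming rule required.

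None of the 34 measured members of the epithelial list rose in 344SQ, and adjusted over the list alone 20 fell. The list's median change was -0.52 (camera adjusted p = 1.88e-17; adjusted p = 0.269 with an estimated correlation). St14, which encodes the membrane protease matriptase, fell by 4.35 on the log2 scale and Ap1m2, an epithelial adaptor subunit for vesicle sorting, by 4.30. The adhesion molecule gene Epcam fell by 3.82 (SE 0.33, adjusted p = 2.49e-05), from 13.45 ± 0.15 (SD, n = 4) in 393P to 9.63 ± 0.90 in 344SQ. Its other probe set had a change of -0.45 (adjusted p = 0.0246). The claudin genes Cldn4, Cldn3 and Cldn7, chosen after their values were seen, encode tight junction proteins and fell as well (log2 changes -4.73, -4.09 and -3.80). The list did not move as a whole. Cdh1, which encodes E-cadherin, was at 13.51 ± 0.19 in 344SQ and 13.39 ± 0.15 in 393P (log2 change 0.12 ± 0.13, adjusted p = 0.635). The keratin genes Krt8 and Krt18, also chosen after their values were seen, had changes of -0.00 and -0.06.

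**Figure D1:**
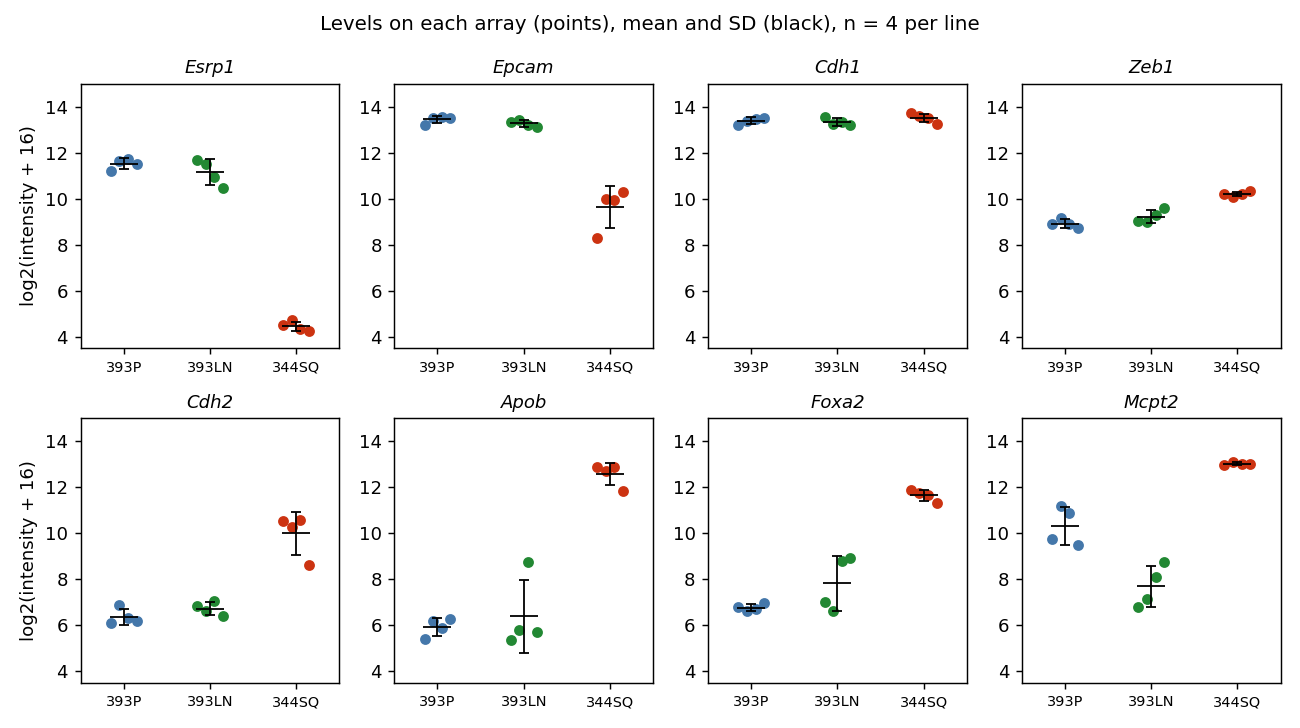
Level of 8 genes on each array as log2(intensity + 16), with the 3 lines on the horizontal axis, 4 points per line, and the mean and SD in black. Esrp1 lies at 4.45 in 344SQ against 11.51 in 393P and Epcam at 9.63 against 13.45, while Cdh1 lies at 13.51 against 13.39.

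Genes of mesenchymal transition rose in part. Of 31 measured members, 8 rose and 1 fell (10 and 3 when adjusted over the list alone), with a median change of 0.25 (camera adjusted p = 0.0142; adjusted p = 0.745 with an estimated correlation). The N-cadherin gene Cdh2 rose by 3.62 ± 0.37 (12.3-fold, adjusted p = 8.06e-05) and S100a4, which encodes a calcium-binding protein of motile cells, by 2.11 ± 0.39. The transcription factor genes Zeb1 and Snai2 rose by 1.29 ± 0.14 and 0.94 ± 0.19 and the intermediate filament gene Vim by 1.25 ± 0.26 (adjusted p = 0.00914). The tropomyosin gene Tpm2 went the other way and fell by 1.41. Twist1 rose by 1.02 (adjusted p = 0.0221) and Snai1 by 0.48 (adjusted p = 0.0394), calls that ended when any of 5 and 7 arrays was left out with highest adjusted p of 0.0685 and 0.112. Zeb2 had a change of 0.44 ± 0.14 (adjusted p = 0.0617). Of 22 collagen and fibrillar matrix genes 4 rose and none fell (6 and 0 when adjusted over the list alone). Among them were Col6a1 and Col6a2, by 1.02 and 1.09, and the crosslinking enzyme gene Lox, by 0.94. Their list's median was 0.26 (camera adjusted p = 0.00321; adjusted p = 0.745 with an estimated correlation). The fibroblast list had a median of 0.23 (camera adjusted p = 0.0193; adjusted p = 0.745 with an estimated correlation), although 0 of its 19 members passed the test by itself. Its call ended without 344SQ replicate 3 or 393P replicate 4 (adjusted p = 0.0985 and 0.118).

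**Figure D2:**
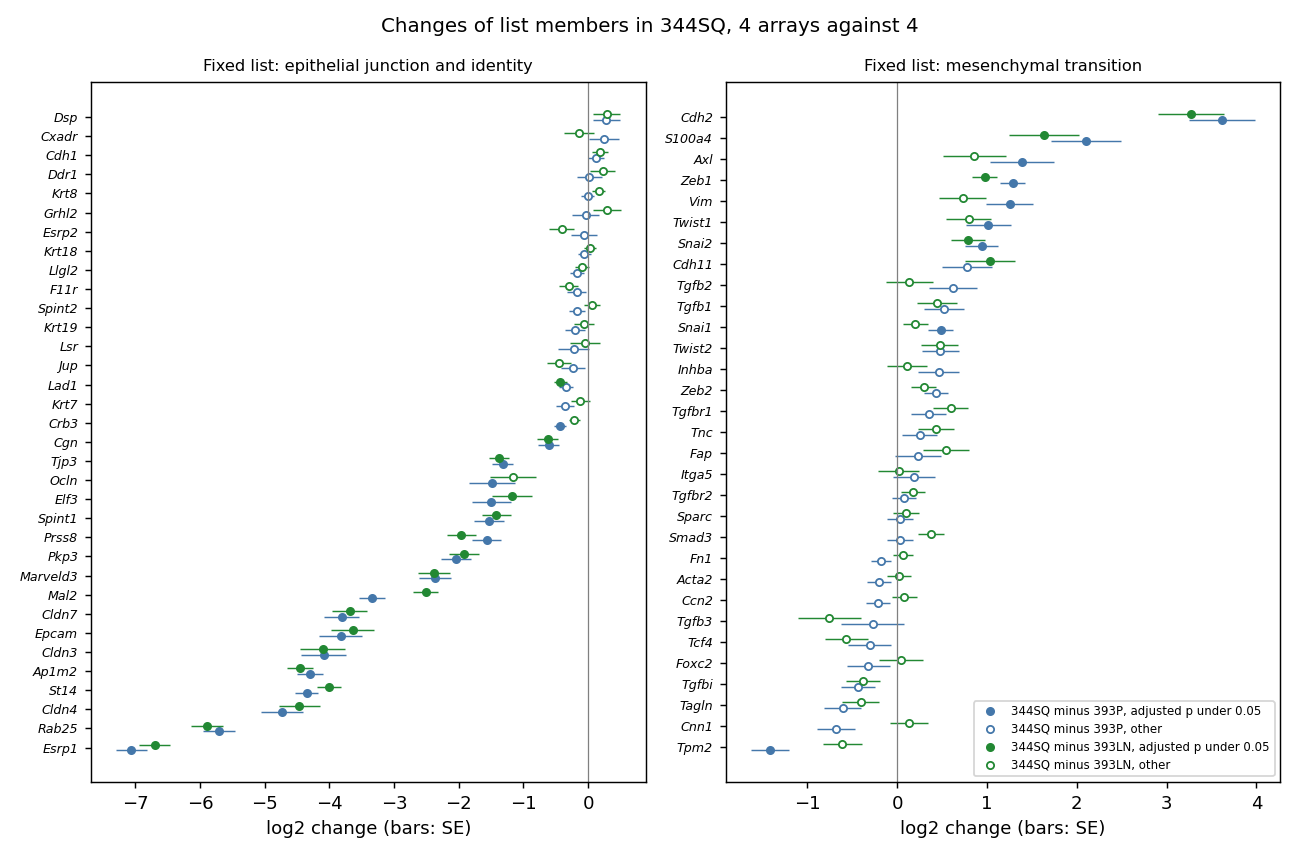
Log2 change of each measured member of the epithelial list (left, 34 genes) and the mesenchymal list (right, 31 genes) in 344SQ, against 393P in blue and against 393LN in green, with bars of 1 SE; filled points have an adjusted p under 0.05. Esrp1 and Rab25 lie lowest on the left and Cdh2 highest on the right.

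Of 20 genes of foregut and gut lineage 6 rose in 344SQ and 1 fell (7 and 1 when adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.0092; adjusted p = 0.745 with an estimated correlation). The pancreatic and duodenal factor gene Pdx1 rose by 3.10 ± 0.46 (adjusted p = 0.00122), the endoderm factor gene Gata6 by 1.84 ± 0.27 and Onecut2 by 1.06 ± 0.21. Vil1, the brush border villin gene, fell by 3.07, a call that ended without 1 of 2 arrays (highest adjusted p 0.0511). Outside the list, Vsig1, a stomach adhesion molecule gene, was 47.2-fold higher and Cym, which encodes the milk-clotting stomach protease chymosin, 12.6-fold higher. The log2 change of Cym was 3.66 with all arrays and 4.48 without 344SQ replicate 4, where its level was 7.74 against 10.32 to 11.69 on the other 344SQ arrays. Krt23, Irx3, Tspan12, Avil and Nrn1 were 42.2-fold, 15.2-fold, 13.7-fold, 13.7-fold and 12.4-fold higher. The lung epithelial list split, with 3 members that rose and 3 that fell among 24 (median 0.03, camera adjusted p = 0.916). Nkx2-1, the lung lineage factor gene, was near the floor in all 3 lines, at 4.24, 4.18 and 4.15, and Sftpc lay at 7.13 ± 0.17 in 344SQ and 6.82 ± 0.23 in 393P (adjusted p = 0.302).

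Large falls were also seen in other genes. S100a14 was 71.8-fold lower, Cwh43 61.6-fold, Lama3, a laminin chain of hemidesmosomes, 39.1-fold, and Nnat 41.0-fold. The serine protease genes Tmprss11e and Klk8 were 37.5-fold and 32.8-fold lower, the ubiquitin ligase gene Rnf144b 27.5-fold and the membrane mucin gene Muc4 27.0-fold. Of 22 skin and squamous markers 5 fell and none rose (5 and 0 when adjusted over the list alone), led by the desmosomal plakophilin gene Pkp1 (fell by 3.02), the keratin gene Krt6a (fell by 3.76, and by 4.36 without 344SQ replicate 1) and involucrin, Ivl (fell by 1.97). The list's median was -0.20 (camera adjusted p = 0.0166; adjusted p = 0.745 with an estimated correlation). The mean level of the list differed between arrays of one line, at 8.99 on 393P replicate 3 and at most 7.87 on the other 3 393P arrays. The call ended without that array (adjusted p = 0.184) and without 344SQ replicate 2 or 3 (0.0582 and 0.0712).

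Several lists of immune cells and that of the interferon response were lower in 344SQ, with few members that passed the test by themselves. The MHC class I antigen presentation list had a median of -0.86 (2 of 14 members fell, and 2 when adjusted over the list alone; camera adjusted p = 0.000242; adjusted p = 0.745 with an estimated correlation), and its member H2-Q2 fell by 2.24 ± 0.44. The interferon response list had a median of -0.66 (2 of 32 fell, and 2 when adjusted over the list alone; camera adjusted p = 0.000276; adjusted p = 0.745 with an estimated correlation); its members Usp18 and Isg20 fell by 2.84 and 1.51, and Usp18 by 2.20 without 344SQ replicate 4. These lists varied within 344SQ: the mean level of the interferon list was 10.36 on replicate 1, 9.44 on replicate 2, 9.05 on replicate 3 and 7.64 on replicate 4, against 9.36 to 10.25 in 393P. Without 344SQ replicate 4 the interferon median moved from -0.66 to -0.29. Macrophage and monocyte markers had a median of -0.55 (3 of 26 fell, and 3 when adjusted over the list alone; camera adjusted p = 0.0119; adjusted p = 0.745 with an estimated correlation), and Aif1 and Tyrobp fell by 1.26 and 0.92. Neutrophil markers had one of -0.37 (4 of 16 fell, 5 when adjusted over the list alone; camera adjusted p = 0.014; adjusted p = 0.745 with an estimated correlation), led by the cytokine gene Il1b (fell by 1.34) and the deiminase gene Padi4 (fell by 3.36). On 344SQ replicate 4 the neutrophil list's mean was 9.32, inside the 393P range of 8.86 to 9.41, and Padi4 was at 10.04 against 5.40 to 6.35 on the other 344SQ arrays. Without that array its change was -4.36. The macrophage call ended without 393P replicate 2 or 4 (0.0623 and 0.0561) and the neutrophil call without 344SQ replicate 3 or 393P replicate 4 (0.102 and 0.0651). Dendritic cell and MHC class II genes had a median of -0.37 (1 of 17 fell, and 1 when adjusted over the list alone; camera adjusted p = 0.0443; adjusted p = 0.745 with an estimated correlation), a call that ended without any of 5 arrays (highest adjusted p 0.264). T and NK cell markers (median -0.05, camera adjusted p = 0.916) and B and plasma cell markers (median 0.07, adjusted p = 0.769) did not pass. Of 24 T and NK cell markers 2 rose, Cd2 and Xcl1, and 0 fell (2 and 0 when adjusted over the list alone). The call of Xcl1 ended without any of 5 arrays (highest adjusted p 0.0663).

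**Figure D3:**
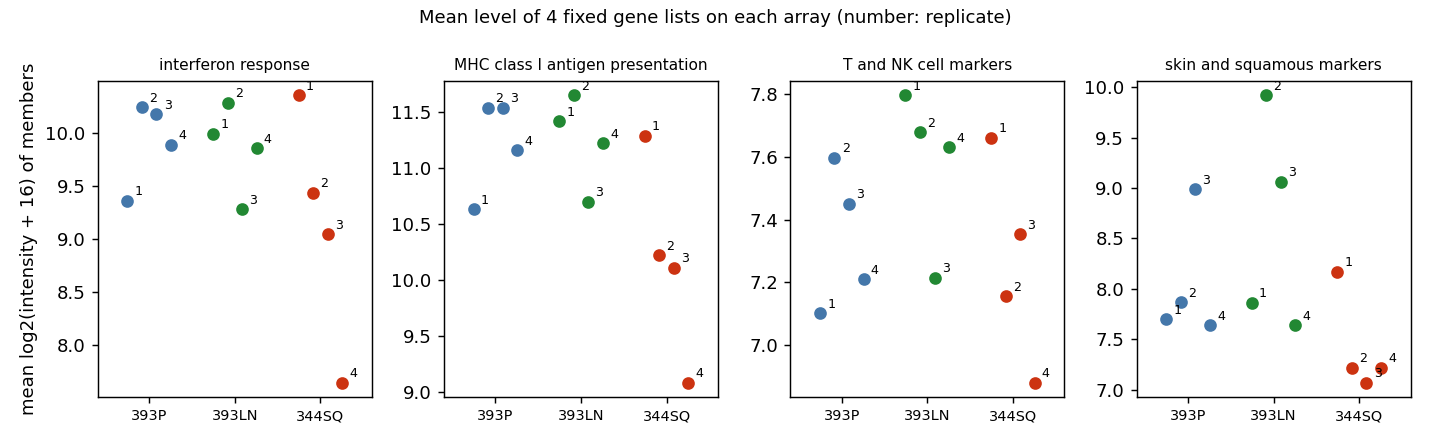
Mean log2(intensity + 16) over the measured members of 4 gene lists on each of the 12 arrays, grouped by line on the horizontal axis, with the replicate number beside each point. The interferon list spans 7.64 to 10.36 in 344SQ, and its lowest value is that of replicate 4.

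Of 39 cell cycle genes 8 fell and 1 rose (12 and 1 when adjusted over the list alone; median -0.18, camera adjusted p = 0.0017; adjusted p = 0.745 with an estimated correlation). The replication licensing gene Mcm2 fell by 0.59 and the ubiquitin-conjugating gene Ube2c by 0.82, whereas Rrm2, the ribonucleotide reductase subunit, rose by 1.14. Among signalling genes, the receptor gene Erbb3 fell by 2.29 ± 0.17 (adjusted p = 8.95e-06), the Wnt ligand genes Wnt7b and Wnt7a by 1.69 and 1.12, the Notch modifier gene Lfng by 1.19 and the transcription factor gene Jun by 1.66. Notch2 rose by 0.62 and Notch3 fell by 0.66, while the Notch ligand gene Jag2 was level at 9.64 ± 0.16 and 9.57 ± 0.08 (adjusted p = 0.756). Of 29 hypoxia and glycolysis genes 2 rose and 6 fell (2 and 7 when adjusted over the list alone): the carbonic anhydrase gene Car9 rose by 2.91, and Kdm3a and P4ha2 fell by 0.75 and 1.09. Of 37 chemokine and cytokine genes 2 rose and 6 fell (2 and 10 when adjusted over the list alone): the alarmin gene Il33 rose by 2.21, and Cxcl5 and Cxcl16 fell by 2.63 and 1.38. The endothelial phosphatase gene Ptprb rose by 2.47, and the protease gene Plau fell by 2.39. The Notch, Wnt, hypoxia and chemokine lists did not pass (camera adjusted p = 0.906, 0.916, 0.05001 and 0.05001). The sex chromosome gene list did (8 genes, 2 rose, 3 when adjusted over the list alone; median 0.77, camera adjusted p = 0.0142; adjusted p = 0.742 with an estimated correlation). Its members varied within lines: Xist, chosen after its values were seen, was at 6.82 on 344SQ replicate 3 and at 10.69 to 11.94 on the other 344SQ arrays.

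Of the named genes that passed here, 64 have other probe sets. For 30 of them no other probe set passed, among them Apob, Lama3, Pdx1, Lfng, Notch2, Wnt7a, Wnt7b, Erbb3 and Krt6a, and for 0 another passed the opposite way. These cases differ. The other probe set of Wnt7b fell by a like amount (-1.57, adjusted p = 0.0872). Those of Lama3, Pdx1 and Erbb3 were dim, with means of 5.05, 4.97 and 5.07, and can show little. Those of Wnt7a had changes of 0.09 and 0.27 and that of Notch2 one of 0.10.

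In all, 884 genes were higher and 1023 lower in 344SQ than in 393P, of which 639 changed at least 2-fold (278 higher, 361 lower). For 16.7% of genes the 4 values of one line lay all above those of the other, where chance gives 2.86%. Without 344SQ replicate 2 or 3 the number higher was 581 or 565, and without 393P replicate 2 or 3 the number lower was 664 or 654. With the level of Xist as a covariate, an alternative added after seeing the data, 511 genes were lower. Xist was high on most 344SQ arrays and low on most 393P arrays, so this covariate partly follows the line.

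The comparison of 344SQ with 393LN set the highly metastatic line against the intermediate one. The epithelial list members Esrp1 and Rab25 were lower here too, and so were S100a14 and Lama3. Esrp1 was 104-fold lower (log2 change -6.70 ± 0.24, n = 4 per line, adjusted p = 1.73e-08), S100a14 79.1-fold (-6.31 ± 0.19), Rab25 59.4-fold (-5.89 ± 0.25) and Lama3 39.0-fold (-5.29 ± 0.20). Apob was 72.4-fold higher (6.18 ± 0.61, adjusted p = 7.37e-05), Sftpb 39.7-fold (5.31 ± 0.35) and Vsig1 32.6-fold (5.03 ± 0.78). Without 393LN replicate 3 the changes of Apob and Vsig1 were 6.97 and 6.02. The mast cell protease genes Mcpt2 and Mcpt1 were 40.6-fold and 16.5-fold higher (5.34 ± 0.44 and 4.04 ± 0.44, adjusted p = 1.76e-05 and 0.000161). The annexin gene Anxa10, expressed in stomach, was 19.4-fold higher.

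Of 34 epithelial genes 17 fell and none rose (18 and 0 when adjusted over the list alone; median -0.54, camera adjusted p = 6.12e-13; adjusted p = 0.577 with an estimated correlation), and Epcam and Ap1m2 had changes of -3.64 and -4.46. Cdh1 had a change of 0.18 ± 0.13 (adjusted p = 0.397). Other large falls were in Cwh43 (by 31.1-fold), the ubiquitin ligase gene Rnf144b (29.8-fold), the myosin gene Myo3b (27.1-fold) and Tmprss11e (25.4-fold). Of 31 mesenchymal genes 5 rose (7 when adjusted over the list alone; median 0.20, camera adjusted p = 0.00116; adjusted p = 0.743 with an estimated correlation), among them Cdh2 by 3.27 and Zeb1 by 0.98. Vim had a change of 0.73 ± 0.26 (adjusted p = 0.0965) and Twist1 one of 0.80 ± 0.25 (adjusted p = 0.0621). Of 22 collagen genes 2 rose, Col6a1 and Col6a2, by 1.22 and 1.26 (2 when adjusted over the list alone; median 0.26, camera adjusted p = 0.00651; adjusted p = 0.743 with an estimated correlation). The collagen list's mean was 11.82 on 393LN replicate 4 and 11.24 to 11.27 on the other 393LN arrays, against 11.51 to 11.83 in 344SQ; the epithelial list's mean on replicate 4 was 11.13, the lowest of 393LN. The fibroblast list had a median of 0.27 with 0 of 19 members past the test (camera adjusted p = 0.0144; adjusted p = 0.743 with an estimated correlation), a call that ended without 344SQ replicate 3 or 393LN replicate 3 (0.0748 and 0.0982).

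Gut lineage genes rose in 6 of 20 cases (6 when adjusted over the list alone, with 1 that fell), and the list's median was 0.29 (camera adjusted p = 0.00179; adjusted p = 0.607 with an estimated correlation). The liver and gut factor gene Hnf4a rose by 2.48, Pdx1 by 2.36, the trefoil peptide gene Tff1 by 2.04 and Gata6 by 1.40. Foxa2, a member of the lung epithelial list, rose by 3.83. In that list 2 members rose and 4 fell among 24 (camera adjusted p = 0.849). Skin and squamous markers had a median of -1.15 (5 of 22 fell and 1 rose, and the same numbers when adjusted over the list alone; camera adjusted p = 0.000504; adjusted p = 0.743 with an estimated correlation), and Pkp1 and Krt6a were 9.55-fold and 10.6-fold lower and Sprr1a 2.10-fold higher; the log2 change of Krt6a was -3.997 without 344SQ replicate 1. The mean level of this list was 9.92 and 9.06 on 393LN replicates 2 and 3 and 7.86 and 7.64 on replicates 1 and 4. MHC class I genes had a median of -0.95 (1 of 14 fell, 2 when adjusted over the list alone; camera adjusted p = 0.000504; adjusted p = 0.743 with an estimated correlation). The interferon list had a median of -0.62 (4 of 32 fell, and 4 when adjusted over the list alone; camera adjusted p = 0.0163; adjusted p = 0.857 with an estimated correlation). Its call ended without 344SQ replicate 4 (median -0.21, adjusted p = 0.425), 344SQ replicate 3 (0.0645) or 393LN replicate 2 (0.145). Cell cycle genes had a median of -0.26 (6 of 39 fell, 8 when adjusted over the list alone; camera adjusted p = 0.00651; adjusted p = 0.743 with an estimated correlation), a call that ended without 344SQ replicate 1 (adjusted p = 0.0773). The list of MAPK feedback targets had a median of 0.22, with 4 of 25 members that rose and 2 that fell (5 and 2 when adjusted over the list alone; camera adjusted p = 0.0245; adjusted p = 0.743 with an estimated correlation). Its member Myc fell by 1.27, and the list's call ended without 344SQ replicate 3 or 4 (adjusted p = 0.0688 and 0.0504). Among growth factor genes, Fgf1 and Pdgfc rose by 1.34 and 1.22 and Pdgfa fell by 0.89.

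For 35 of 62 named genes with other probe sets no other one passed, among them Apob, Lama3, Epcam, Zeb1, Rnf144b, Gata6, Pdx1 and Krt6a. Another Epcam probe set had a change of -0.18 (adjusted p = 0.381).

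Against 393LN, 725 genes were higher and 1259 lower in 344SQ, so 36.5% were higher, and 46.4% after quantile normalization. Of these genes 561 changed at least 2-fold (248 higher, 313 lower); the values of the lines did not overlap for 17.4% of genes, where chance gives 2.86%. Without 344SQ replicate 2 the counts were 427 and 740, without 393LN replicate 2 the number higher was 482, and without 393LN replicate 3 the number lower was 820. With Xist as a covariate they were 195 and 226, with 305 at least 2-fold. Xist was at 10.69 to 11.94 on 344SQ replicates 1, 2 and 4 and at 6.82 on replicate 3. In 393LN it was at 6.78 to 7.04. This covariate therefore largely follows the line. The fewer genes may be line differences that it takes up or effects of whatever sets the Xist level, such as the sex of the hosts, which is not given. These cannot be told apart here.

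Against both 393 lines, 404 genes were higher and 581 lower in 344SQ, and 2 genes went opposite ways. Apob, Sftpb, Vsig1, Foxa2, the actin-binding protein gene Avil and Cym were the strongest of the first kind, and Esrp1, S100a14, Rab25, Lama3, Cwh43 and Rnf144b of the second. Both comparisons use the same 344SQ arrays. Data simulated with no effect gave 0 genes each way in 50 runs (highest 0), but with no effect few genes can pass in either comparison. These runs therefore cannot show how much the shared arrays add to the overlap. Independent lists of these sizes share 35.2 and 70.8. With the 344SQ arrays split into 2 and 2, one pair for each comparison, 132 to 166 genes were higher and 214 to 240 lower, where independent lists share at most 12.5 and 26.8. Without 344SQ replicate 2 the counts were 258 and 373, and with Xist as a covariate 152 and 167. Xist largely follows the line in 344SQ against 393LN, so the last fall cannot be told from line differences that the covariate takes up.

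The comparison of 393LN with 393P set a nodal metastasis line against a primary tumour line of the same mouse. It gave the fewest differences. In 393LN the urea transporter gene Slc14a1 was 15.2-fold higher (log2 change 3.93 ± 0.46, n = 4 per line, adjusted p = 0.00237). The cation channel gene Trpa1 was 8.42-fold higher (3.07 ± 0.36, adjusted p = 0.00233), Bst1, which encodes a surface ADP-ribosyl cyclase, 4.12-fold and the centromere protein gene Cenpv 3.83-fold. Pvt1, a noncoding RNA gene next to Myc, was 3.16-fold higher by its brightest probe set, but its 4 others had changes of -0.48, 0.01, -0.08 and -0.32, and none passed. Myc had a change of 0.88 ± 0.27 (adjusted p = 0.115). The angiomotin gene Amot, which encodes a junction protein of Hippo signalling, was 9.11-fold lower (-3.19 ± 0.36, adjusted p = 0.00233) by its brightest probe set, while its 2 others had changes of -0.07 and -0.18 (adjusted p = 0.922 and 0.797). Capsl was 6.07-fold and Mcpt2 6.22-fold lower (adjusted p = 0.0127).

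Further falls in 393LN were in the chloride channel regulator gene Clca3b (by 5.46-fold), the kallikrein gene Klk8 (3.95-fold), the cadherin gene Cdh13 (3.84-fold), the cornified envelope gene Sprr1a (2.46-fold), Wnt7a (2.33-fold) and the basement membrane gene Nid1 (1.73-fold). Irx3, Bnc1 and Acsl6 were 4.85-fold, 3.47-fold and 3.34-fold higher and Mcpt1, Rps4l and Adgrg2 4.27-fold, 5.31-fold and 4.76-fold lower. These calls ended when any of 2, 3, 9, 5, 1 and 2 arrays was left out, with highest adjusted p of 0.0631, 0.0592, 0.115, 0.086, 0.0531 and 0.0571. The epithelial list had 1 of 34 members that fell (median -0.12, camera adjusted p = 0.153) and the mesenchymal list 0 of 31 (median 0.01, adjusted p = 0.698). Epcam, Zeb1 and Cdh2 had changes of -0.18 ± 0.33, 0.31 ± 0.14 and 0.35 ± 0.37 (adjusted p = 0.863, 0.308 and 0.729). Chemokines and inflammatory cytokines had a median of -0.09 (1 of 37 fell, Ccl17, and 1 when adjusted over the list alone; camera adjusted p = 0.0431; adjusted p = 0.998 with an estimated correlation). Sex chromosome genes had one of 0.56 (2 of 8 rose, Eif2s3x and Kdm5c, 3 when adjusted over the list alone; camera adjusted p = 0.0431; adjusted p = 0.998 with an estimated correlation). These list calls ended without any of 5 and 4 arrays (highest adjusted p 0.326 and 0.0751), and those of Ccl17, Eif2s3x and Kdm5c without any of 5, 7 and 11 (highest 0.0611, 0.0923 and 0.121).

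For 9 of 15 named genes with other probe sets no other one passed, among them also Wnt7a, Nid1, Adgrg2 and Kdm5c. The sample numbers in the titles lie in a lower range for 393LN than for the other lines, so a batch, if they mark one, cannot be told from the line.

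In 393LN 319 genes were higher and 127 lower than in 393P, and 103 changed at least 2-fold (51 higher, 52 lower), so 71.5% of the genes past the test were higher; after quantile normalization that share was 58.7%. The values did not overlap for 10.3% of genes, where chance gives 2.86%. The counts changed when an array was left out, and the number higher was at most 311 whichever array that was. It was 192 and 105 without 393LN replicates 2 and 3 and 140, 108 and 127 without 393P replicates 2, 3 and 4. The number lower was 67, 62 and 78 without 393LN replicates 2, 3 and 4 and 53, 48 and 65 without 393P replicates 2, 3 and 4. Without 393LN replicate 3 or 393P replicate 3, 53 or 64 genes were at least 2-fold. In a fit on only these 8 arrays 118 genes were higher and 56 lower, and with Xist as a covariate 147 and 80. Of the 1907 genes that differed between 344SQ and 393P, the mean of 393LN lay nearer 393P for 1375 (72.1%).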

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

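Of 261 sets of 4 arrays of one line (105 for list means, 147 for genes, 9 for array measures), 32 had 1 array whose gap to the nearest other took more of the set's range than Dixon's 95% critical value; chance gives about 1 in 20, here 13. Of these 32, 12 were list means, 18 genes and 2 array measures. The tests of the 3 patterns weighed below were chosen only after those patterns were seen; the regroupings of arrays were planned before.

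List means stood apart on 393LN replicate 1 for basement membrane (9.82, nearest 9.57), endothelial (9.09, nearest 8.73) and skeletal muscle genes (8.85, nearest 7.40). On 393LN replicate 4 collagens were at 11.82 (nearest 11.27), hypoxia genes at 11.04 (nearest 11.14) and epithelial genes at 11.13 (nearest 11.49). Adipocyte markers were at 7.74 on 393LN replicate 2 (nearest 8.35) and matrix proteases at 10.10 on 393LN replicate 3 (nearest 10.30). Blood markers were at 7.91 (nearest 7.74) and epithelial genes at 11.23 (nearest 11.57) on 393P replicate 1. Skin markers were at 8.17 on 344SQ replicate 1 (nearest 7.22), and retinoid and xenobiotic metabolism genes at 8.83 on 344SQ replicate 4 (nearest 9.09).

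Single genes stood apart in 344SQ: Epcam at 8.31 (nearest 9.95), Muc4 at 5.92 (nearest 5.51), Cenpv at 10.36 (nearest 10.65) and Nkx2-1 at 4.57 (nearest 4.14) on replicate 1, Lama3 at 6.45 on replicate 3 (nearest 6.86), and Sftpb at 11.43 (nearest 13.20), Cdh2 at 8.63 (nearest 10.28) and Tmprss11e at 7.28 (nearest 5.90) on replicate 4. In 393LN they were Apob at 8.76 (nearest 5.79), Krt23 at 10.74 (nearest 7.82) and Jag2 at 9.75 (nearest 9.58) on replicate 3 and Nkx2-1 at 4.47 (nearest 4.09) on replicate 4. In 393P they were Epcam at 13.22 (nearest 13.51) and Rab25 at 11.49 (nearest 11.83) on replicate 1, Cenpv at 8.08 on replicate 2 (nearest 8.73), and Xist at 10.92 (nearest 7.35), Slc14a1 at 7.85 (nearest 6.10) and Nkx2-1 at 4.31 (nearest 4.10) on replicate 4. The actin 3' to 5' ratio was 1.47 on 393P replicate 1 (nearest 1.05), and 1323 probe sets lay at the floor on 344SQ replicate 2 (nearest 1228).

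Of the 35 ways to divide 8 arrays into 4 and 4, 1, the real one, gave as many genes in each comparison. The smallest p that such regroupings can give is 0.0286. Every other way mixes the lines, so differences between lines widen the spread and few genes can pass. The regroupings thus cannot exclude chance by themselves. The real values were 1907 for 344SQ against 393P, 1984 for 344SQ against 393LN and 446 for 393LN against 393P, and the highest others were 2, 0 and 1.

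The epithelial genes that were lower in 344SQ than in both 393 lines may reflect fewer tumour cells in those samples, uneven RNA quality or a property of the line. Fewer tumour cells would lower all epithelial genes alike, but 10 of the 34 members had a 95% interval of their change against 393P wholly above -0.5 while the median of the members that differed was -2.85, which speaks against it there; this was not run against 393LN. With the actin ratio as a covariate the list's median against 393P was -0.51 (camera adjusted p = 9.17e-18, range over the alternatives 8.15e-20 to 0.269). This covariate could hardly have removed the fall. The ratio was 1.04 to 1.19 on all arrays but 393P replicate 1 (1.47), whose epithelial mean of 11.23 was the lowest of 393P. So the ratio itself does not follow the line, and unevenness in RNA quality that it misses was not tested. The biological reading, a difference between the lines, stays open, as line, mouse and metastatic class cannot be separated here.

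The lower interferon list in 344SQ may rest on a single array or on fewer immune cells. Without 344SQ replicate 4 its median was -0.29 against 393P, which leaves that open, and -0.21 against 393LN, where the call ended and a single array is thus a candidate explanation (adjusted p range over the alternatives 2.64e-10 to 0.745 and 7.51e-07 to 0.857). Fewer immune cells of every type would lower T and NK markers too. Of 24 measured, 2 rose and 0 fell against 393P. The mean change of 10 bright ones was -0.31 (95% interval -0.875 to 0.255), which cannot tell. A difference in interferon signalling between the lines was not tested apart from these.

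Xist differed within lines, at 6.82 on 344SQ replicate 3 against 10.69 to 11.94 on the others, and at 10.92 on 393P replicate 4. A mislabelled sample is unlikely, as 12 of 12 arrays correlated best with their own line. Host animals of both sexes could give such levels and would leave each Y gene highest of its line on 344SQ replicate 3 and lowest of its line on 393P replicate 4. This held for 3 of 3 Y genes (Eif2s3y at 10.33 and 4.88), but the test used only the arrays that prompted it. On other arrays Xist and Y genes did not simply run opposite. 344SQ replicate 2 had Xist at 11.03 and Eif2s3y at 10.07, and 393P replicate 1 Xist at 7.04 and Eif2s3y at 6.58. The samples mix tumour and host cells, and the levels in tumour cells alone are not known. Xist beside Y genes on the same array therefore does not count against hosts of both sexes, and the explanation stays open. The sex of the hosts is not given in the sources used here.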

How the results depend on the processing

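The direction of every named gene and list that passed its test held in each alternative that gave a value for it (0 reversed). Settings that gave only counts, such as probe sets tested singly and the comparison of ranks, checked no direction. Some other probe sets of named genes went the opposite way, such as a Pvt1 probe set in 393LN against 393P (-0.48). None of them passed that way. Of 293 named gene results, 3036 of 3516 values with an array left out and 3470 of 3737 under other settings stayed past the threshold; of 25 list results, 269 of 300 and 308 of 375 did. Of 6412 values for results that had not passed, 184 passed under an alternative. Genes near the floor limit what a fold can show. No paired analysis was possible because the labels give no pairing of arrays. Except where named below, the cause was not tested.

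With each array left out in turn, 344SQ against 393P gave 565 to 903 genes higher, 654 to 1053 lower, 569 to 641 at least 2-fold and 9 to 16 lists. For 344SQ against 393LN these were 427 to 922, 740 to 1559, 489 to 623 and 7 to 11, and for 393LN against 393P 105 to 311, 48 to 166, 53 to 134 and 0 to 8. Against both lines 258 to 443 genes were higher and 373 to 639 lower. Fewer arrays leave fewer degrees of freedom, but this does not cover the counts that rose. Without 393P replicate 1, 344SQ against 393LN gave 922 higher and 1559 lower, where all arrays gave 725 and 1259.

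Without the dimmest 50% of genes, 422 genes (639 with all) were at least 2-fold in 344SQ against 393P and 365 (561) against 393LN, from fewer genes tested. Probe sets tested singly, which are more than genes, gave 1345 higher (884) and 973 at least 2-fold against 393P, 851 at least 2-fold against 393LN, and 482 higher (319) and 175 at least 2-fold (103) for 393LN against 393P. A fit on only the 8 arrays compared, with fewer degrees of freedom, gave 118 higher, 56 lower (127), 67 at least 2-fold and 0 lists (2) for 393LN against 393P. Array weights gave 1544 higher and 1776 lower (1023) in 344SQ against 393P, and 552 higher, 331 lower and 4 lists for 393LN against 393P. Genes whose 4 values lay all above the other 4, a rule with no adjustment, were 1477 higher and 1568 lower in 344SQ against 393P, 1222 (725) and 1946 (1259) against 393LN, 1218 and 649 for 393LN against 393P, and 610 (404) higher in 344SQ against both.

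The number of lists past the test fell from 13, 10 and 2 to 0, 0 and 0 with an estimated correlation, and was 2, 2 and 0 with fry in one direction and 25, 24 and 11 in either direction. For 393LN against 393P it was 1 with arrays centred on their median, 0 with a pseudocount of 1, 0 without the less specific probe sets, 1 with the mean of a gene's probe sets and 8 with the actin ratio as a covariate. With the 344SQ arrays in 2 and 2, the genes shared by both comparisons were 132 to 166 higher and 214 to 240 lower (581), from fewer arrays. The level of Xist was added as a covariate, with the actin ratio, after the data were seen. With Xist, 511 genes were lower in 344SQ against 393P. Against 393LN 195 were higher, 226 lower and 305 at least 2-fold, with 19 lists. For 393LN against 393P 147 were higher and 80 lower, and for 344SQ against both lines 152 and 167. Xist largely follows the line in 344SQ against 393LN, so the fewer genes there cannot be told from line differences that the covariate takes up.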

Other observations

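The mast cell and eosinophil list passed in no comparison, although the mast cell protease gene Mcpt2, which is not in it, differed between all 3 lines. All mast cell genes here apart from those the naming rule gave were chosen after their values were seen. Mcpt2 was at 12.98, 13.10, 13.03 and 13.01 on the 4 344SQ arrays, at 6.78, 7.13, 8.12 and 8.75 in 393LN and at 9.76, 11.17, 10.88 and 9.50 in 393P. Cpa3, a mast cell carboxypeptidase gene, was at 8.70, 9.09 and 8.68 on 344SQ replicates 1 to 3 and at 6.58 on replicate 4, and the chymase gene Cma1 at 8.67, 8.94, 8.53 and 6.38. The tryptase gene Tpsab1 was at 12.13, 12.10, 11.15 and 9.28 and rose by 2.87 against 393LN (adjusted p = 0.00942), and by 3.499 without 344SQ replicate 4. Of the list's 13 members 1 rose and 0 fell in 344SQ against 393LN (4 and 0 when adjusted over the list alone; median 0.24, camera adjusted p = 0.057), and 0 rose and 1 fell against 393P (0 and 1; median 0.13, 0.585). The member that fell against 393P was Hdc, the histidine decarboxylase gene (log2 change -0.89, adjusted p = 0.0347), a call that ended without any of 6 arrays (highest adjusted p 0.0913). Against 393LN and 393P the changes of Tpsb2 were 0.16 and 0.13, those of Ms4a2 0.24 and -0.12 and those of Kit -0.15 and -0.22, and none passed.

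Several planned lists passed in no comparison. Integrins had 5 members that rose and 4 that fell among 30 in 344SQ against 393LN (camera adjusted p = 0.153), and genes of retinoid, xenobiotic and glutathione metabolism 5 and 1 among 28 (0.0614). The aldehyde dehydrogenase gene Aldh3a1 rose by 1.04 there and the lipid regulator gene Pparg by 0.95, and the neural adhesion gene Ncam1 by 2.22. Of ErbB ligands and growth factor receptors 2 rose and 4 fell among 29 against 393P (0.916), and Ret fell by 1.11. For 393LN against 393P the T and NK, B and plasma cell and lymph node stromal lists had medians of 0.18, 0.30 and 0.02 (0.211, 0.764 and 0.998).

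A hypothesis set down before its result was seen was that whole chromosomes differ in copy number between the lines, so that their genes move together. Of 20 chromosomes, 1 passed the bound of 0.15 the same way in both 344SQ comparisons: 262 bright genes of chromosome 18 had a median change of 0.172 against 393P and 0.255 against 393LN. All are relative to the median of all bright genes. Per array, relative to each gene's mean, the chromosome's median lay between 0.107 and 0.172 on the 344SQ arrays, between -0.126 and -0.0934 in 393LN and between -0.0353 and -0.0115 in 393P. Over 10000 shufflings of genes between chromosomes the highest value was 0.074 (permutation p = 1e-04, the smallest these can give). A gain of chromosome 18 in 344SQ may explain its shift and was not tested on DNA. Of its genes, 36 were higher and 6 lower in 344SQ than in both lines. Between 393LN and 393P the medians of chromosomes X, 12, 16 and 15 were 0.276, 0.204, 0.152 and -0.174. Per array they ran from 0.0743 to 0.149, 0.00534 to 0.256, -0.03 to 0.197 and -0.16 to 0.00083 in 393LN, and from -0.218 to -0.011, -0.162 to -0.0547, -0.0688 to -0.0281 and 0.0886 to 0.139 in 393P, so the arrays of the lines overlap for chromosome 16.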
